A study of Mus musculus with 6 samples.

How the data were processed

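The deposited table holds counts of reads per exon bin for 6 mouse heart libraries, 3 wild-type and 3 knock-in, made from RNA isolated with a column kit and a NEBNext Ultra II RNA library kit, per the labels' protocols. Per the submitters' processing notes, the authors used the GRCm38.p6 build, STAR, featureCounts, Subread 1.5.2 and DESeq2. Their role, order and settings are not given in the sources used here. The counts are whole numbers without normalization, from 425461 bins that do not overlap on a strand. Libraries were matched to the table's columns by the library numbers in the titles. No column of sample values was left unused.

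Very short bins hold many counts, so a read that spans several bins was counted in each. The sum over a gene's bins is not a number of reads, and genes of many short exons are counted more than once per read. Bins of 3 bases or fewer numbered 13119, of which 714 held at least 300 counts over the 6 libraries. Bins were summed per gene identifier, which gave 48005 identifiers, of which 1194 join overlapping genes of a strand. A joined identifier took the name of its single protein-coding gene, which was possible for 511, and the others were kept out of gene lists. Names, exon numbers, coding positions and transcript GC content came from GENCODE annotation of GRCm38. Of 46606 single-gene identifiers compared with it, 91.4% had the same start and end. Strand use was read from the values: 37 bins of at least 50 bases lay inside a bin of the opposite strand with at least 5 counts per base, and their median coverage was 0.00156 of that bin's, so antisense genes were counted apart. Genes with close copies, such as the hemoglobin genes, Gsta genes and pairs on X and Y, can share reads, and their values are less certain.

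Totals ran from 30329004 to 30625093 counts in the wild-type libraries and from 31989883 to 34016586 in the knock-in libraries. The mitochondrial genome took 11.6% to 14.0% of the counts. Pairs of libraries within a group differed beyond sampling noise (chi-square per degree of freedom 15.1 to 42.9 over genes), so each library was used as a separate sample. The series describes 3 hearts per group. PCR reads without molecular identifiers are not independent molecules, and counting error alone would understate the spread between hearts, which the fitted dispersion covers.

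The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Genes were filtered with filterByExpr by group, which left 13066, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust moderation, glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are knock-in minus wild-type, and each SE is the size of the log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes, except those of Txnip's coding and 3' UTR bins, which use total counts. Of 58 gene lists, 54 had at least 3 tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over the lists. None of the 19 lists past the threshold passed with an estimated correlation. Named genes were Txnip in every library, the 12 largest increases and 12 largest decreases among genes past the threshold with mean CPM of at least 1, no overlap between groups and a name that is not a predicted one, up to 4 members of each list by smallest p, and all tested alpha-arrestin, sex-linked, transgene-linked and strain-variable genes. Some lists are printed with fewer examples, and genes named outside the rule are marked as chosen after their values were seen. Values per library with n under 10 were compared by exact permutation over all assignments of 3 and 3, where the smallest two-sided p is 0.1.

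Coverage along transcripts was the count in the last of 3 equal parts of the exonic length over that in the first, with 10 counts added to each, for 1655 protein-coding genes of at least 4000 exonic bases, 10 bins and 6000 counts. Alternatives fixed in advance were other scalings, DESeq2 1.42.0 on the unfiltered table, limma-voom, other filters and thresholds, no robust moderation, mitochondrial genes left out, each heart left out, camera with an estimated correlation, fry, and windows of 1 and 10 Mb around Txnip. Alternatives added after seeing the data were the highest bin of each gene only, bins whose middle lies in the last 1000 exonic bases only, per-library spline offsets (5 degrees of freedom each) for exonic length and GC content, the 3' to 5' ratio as a covariate, and Txnip from coding bins only. GC content was known for 97.2% of tested genes.

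The steps were tested on simulated data drawn from the real means, dispersions and library sizes of these libraries, with 100 genes changed 1.5-fold and 100 changed 2-fold. Over 12902 tested genes, edgeR recovered 41 of the former and 88 of the latter, with 10.1% false calls. It called none of 50 unchanged lists, and a list shifted by 0.4 on the log2 scale was found. The simulated genes were drawn independently, whereas the estimated correlation within real lists reached 0.83. The simulation thus does not show how often unchanged lists of correlated genes are called. Splits of the real hearts that mixed the groups called 4 to 17 lists. A simulated trend with length of 0.2 per doubling was 0.198 before and 0.00355 after the spline correction. Data handling and plots used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.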

Results

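RNA sequencing was carried out on hearts of 6 C57BL/6 mice, 3 labelled wild-type and Txnip flox and 3 labelled conditional knock-in. In the knock-in Txnip allele the PPXY motifs were changed to AAXA. All 6 are labelled MerCreMer, a Cre recombinase fused to mutated estrogen receptor domains that 4-hydroxytamoxifen switches on, with 4-hydroxytamoxifen treatment. Txnip is an alpha-arrestin that binds thioredoxin and limits glucose uptake, and PPXY motifs are the sites at which WW domains of Nedd4-family ubiquitin ligases bind. The comparison asks which transcripts differ in hearts with this conditional knock-in. The counts do not tell mutant from wild-type Txnip transcripts, so how much of the Txnip was mutant was not measured. The table held 48005 gene identifiers, and the counts summed to 30329004, 30428964 and 30625093 in the wild-type libraries and to 31989883, 33805207 and 34016586 in the knock-in libraries. The series states that its control hearts were shared with another series, and the labels give no batch or date, so a batch and the genotype cannot be told apart.

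Txnip (ENSMUSG00000038393) lies on chromosome 3 at 96557957 to 96561883 (GRCm38, forward strand) and has 8 exons. Its PPxY motifs, PPCY at residues 331 to 334 (96560210 to 96560221) and PPTY at residues 375 to 378 (96560342 to 96560353), both fall in exon 7. Over all bins, Txnip stood at 887, 939 and 886 CPM (counts scaled to a common library size) in the wild-type hearts and at 363, 751 and 670 CPM in the knock-in hearts. The means were 904 ± 30.4 and 595 ± 205 CPM (SD, n = 3 per group, edgeR adjusted p = 0.0698), a log2 difference of -0.60 ± 0.20 (SE) that did not pass the threshold. Exact permutation of the 6 values gave p = 0.1 (two-sided, n = 3 per group), the smallest that 3 against 3 allows. Knock-in replicate 1 held the lowest Txnip level, and without it the difference was -0.36 (edgeR adjusted p = 0.0344, and 0.0809 to 0.181 without another heart). Over the alternatives run for Txnip, adjusted p ranged from 0.00236, with 3' end bins only, where Txnip was 4.53 higher on the log2 scale, to 0.994.

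The coding part and the 3' untranslated region (UTR) of Txnip differed in opposite directions. Over the 7 bins of at least 50 bases that hold only coding sequence, Txnip reached 585 ± 21.1 CPM in wild-type and 304 ± 104 CPM in knock-in hearts (SD, n = 3 per group, exact permutation p = 0.1, two-sided). Over the 2 bins that hold only 3' UTR (96560566 to 96561857, 1292 bases), it reached 4.63 ± 0.755 CPM in wild-type and 89.6 ± 38.9 CPM in knock-in hearts (SD, n = 3 per group, exact permutation p = 0.1, two-sided). Counts per base of the 3' UTR bins were 0.491%, 0.559% and 0.433% of those of the coding bins in the wild-type hearts, and 15.0%, 18.5% and 20.3% in the knock-in hearts. A read is counted in each short coding bin that it spans, which lowers these percentages in both groups. The 526-base bin of exon 1 held 3748 to 4474 counts in wild-type and 1552 to 3219 in knock-in hearts. The 817-base bin of the 3' UTR held 89 to 121 and 1057 to 2931. In a fit with coding bins only, a choice made after seeing the data, the Txnip level fell by 0.88 on the log2 scale (edgeR adjusted p = 0.0173, with the range over alternatives given above).

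**Figure D1:**
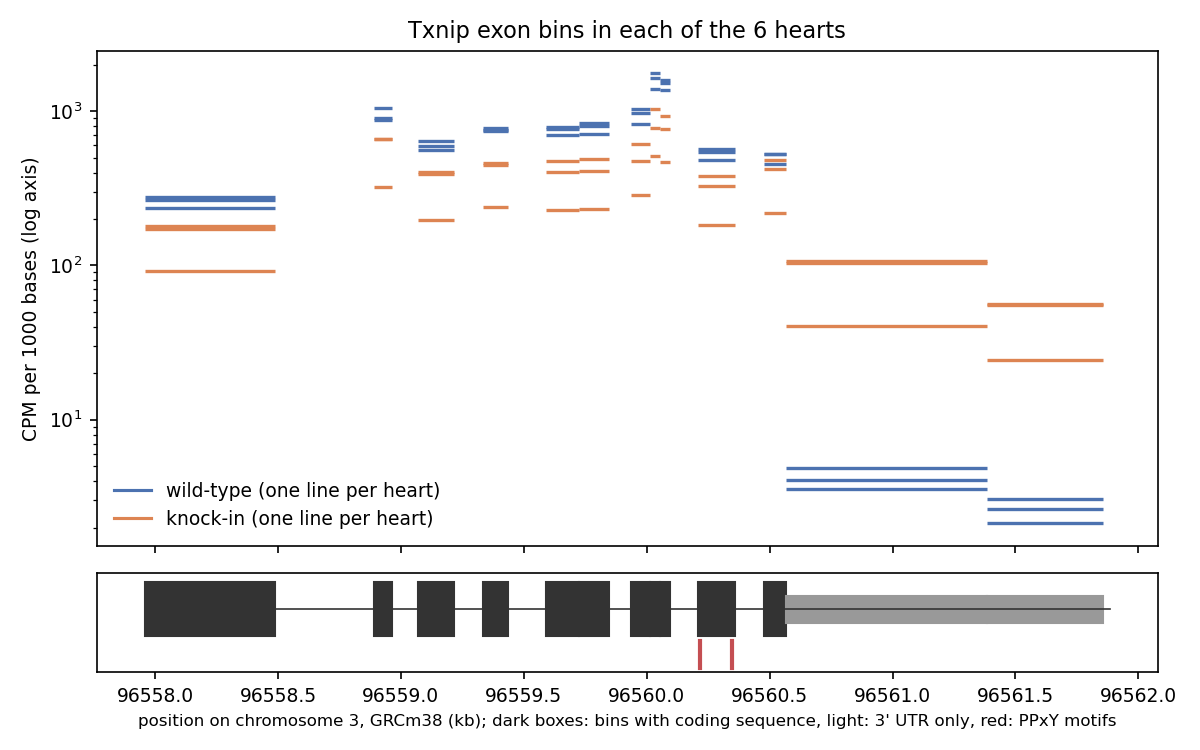
Coverage of Txnip exon bins in each heart, as CPM per 1000 bases on a log axis, against position on chromosome 3, with 1 line per heart and bin. Over the bins that hold only coding sequence every wild-type heart lies above every knock-in heart, and over the 3' UTR below, where they average 4.63 CPM against 89.6 CPM.

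Coverage along other transcripts separated the groups too. In 1655 long genes, the median log2 ratio of 3' to 5' coverage was 0.77, 0.53 and 0.35 in the wild-type libraries and -0.05, -0.18 and -0.11 in the knock-in libraries (exact permutation p = 0.1, two-sided, n = 3 per group). Wild-type libraries thus held relatively more reads near 3' ends, the opposite of what was measured at Txnip. The first principal component, with 46.5% of the variance, placed the wild-type hearts at -38.0, -27.8 and -9.34 and the knock-in hearts at 14.0, 27.9 and 33.3. Knock-in replicate 1 stood apart on the second component, at -34.1 against -4.23 to 18.2 for the others.

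**Figure D2:**
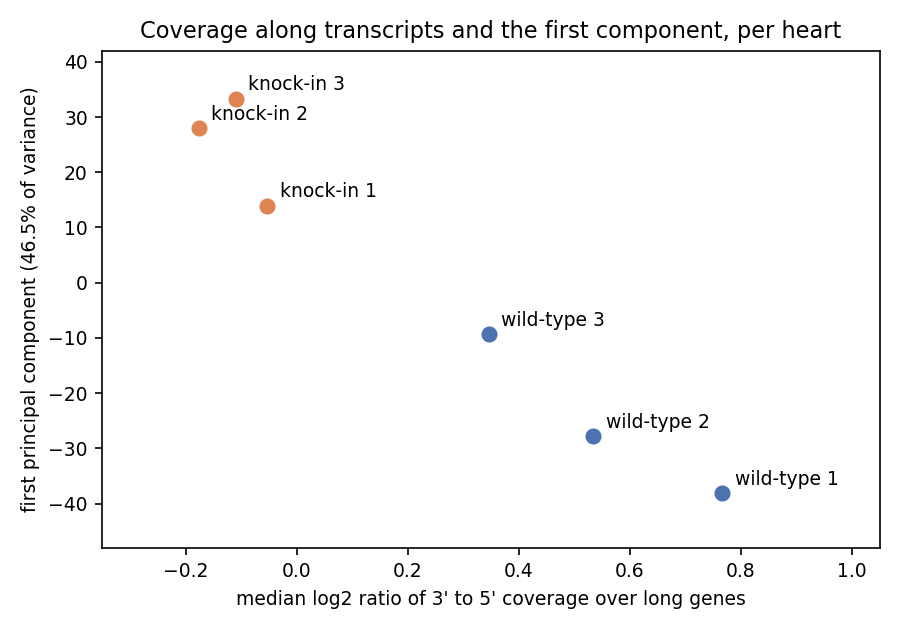
Each point is 1 heart, placed by its median log2 ratio of 3' to 5' coverage over 1655 long genes and by its first principal component (46.5% of variance). The 3 wild-type hearts have ratios from 0.35 to 0.77 and the 3 knock-in hearts from -0.18 to -0.05.

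Between the groups, 881 of 13066 tested genes were higher and 534 were lower in knock-in hearts (edgeR, adjusted p under 0.05), so 62.3% of the calls were higher. The groups did not overlap for 1382 of these 1415 genes and for 30.7% of all tested genes, where chance gives 10% for 3 against 3. Among the genes with the largest changes, Nr4a3 (chromosome 4, 48045153 to 48086447), an orphan nuclear receptor, rose from 2.96 ± 1.44 to 17.8 ± 8.17 CPM (SD, n = 3 per group, edgeR adjusted p = 0.00537). Ppargc1a (chromosome 5, 51454250 to 51567726), a coactivator of mitochondrial biogenesis, rose from 62.1 ± 20.4 to 300.5 ± 142 CPM (SD, n = 3 per group, edgeR adjusted p = 0.00915). Pdk4, a kinase that inhibits pyruvate dehydrogenase, rose 3.31-fold (edgeR adjusted p = 0.0222), and Pdpr, the regulatory subunit of pyruvate dehydrogenase phosphatase, rose 3.14-fold (edgeR adjusted p = 0.00951). Adcy1, Hipk2, Dusp4, Nt5c1a, Uprt, the copper transporter Atp7a, Arid5a and BC067074 rose between 3.27-fold and 4.50-fold. Fos (chromosome 12, 85473890 to 85477273) fell from 14.6 ± 8.87 to 0.881 ± 0.160 CPM (SD, n = 3 per group, edgeR adjusted p = 0.00547). Fosb and Egr1, also immediate early transcription factor genes, fell 12.6-fold and 6.42-fold. Rgs9, Bex1, CAAA01147332.1, Exoc3l, Scand1, Rasl10a, the mitochondrial transfer RNA gene mt-Tp, Spon2 and Nav3 fell between 3.61-fold and 6.34-fold.

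With 1 heart left out, Fos was not past the threshold without knock-in replicate 1 or 3 (edgeR adjusted p = 0.0621 and 0.0675), nor was Ppargc1a or Pdpr without knock-in replicate 3 (0.0583 and 0.0559). Nav3 did not pass without wild-type replicate 1 or 2 or knock-in replicate 2 or 3 (0.0518 to 0.0997). Exoc3l, mt-Tp and BC067074 did not pass without wild-type replicate 1 or knock-in replicate 2 (0.0538 to 0.0809), nor BC067074 without wild-type replicate 2 (0.0625). Pdk4 passed only without wild-type replicate 3 (0.0531 to 0.120 otherwise). Fosb passed only without wild-type replicate 3 or knock-in replicate 1 (0.0532 to 0.0709 otherwise). Egr1 did not pass without knock-in replicate 1 or 3 (0.0619 and 0.105). With 3' end bins only, Ppargc1a and Nav3 lost their calls (edgeR adjusted p = 0.0673 and 0.124). With the highest bin, Ppargc1a, Pdk4, Pdpr and Egr1 lost theirs (0.0543 to 0.113), and Pdk4 also after length and GC correction (0.0623). Without a filter on low counts, Nr4a3, Ppargc1a, Pdk4, Pdpr and Egr1 did not pass (0.0509 to 0.144). Fosb did not pass with limma-voom (0.0505).

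The direction of change followed gene length. Of the fifth of genes with the shortest exonic length, 29 were higher and 207 lower, and of the fifth with the longest, 387 were higher and 50 lower. Counted from bins in the last 1000 exonic bases only, chosen after seeing the data, 204 of 10645 tested genes were higher and 184 lower, and 283 of the 1415 calls were kept. Among the 1415, 91.0% of those tested in this fit kept their sign. After correction for length and GC content, also chosen after seeing the data, 1218 were higher and 587 lower, or 67.5% higher, and 1122 of the 1415 calls were kept. With the 3' to 5' ratio as a covariate, edgeR called 3 genes, Fkbp5, Mt2 and Cyp26b1, named after their values were seen and none among the 1415, with 565 genes at an unadjusted p under 0.05. Every wild-type library had a higher ratio than every knock-in library, so this fit could hardly keep a call or a stable sign. Calls that it lost, turned or gained, here and below, therefore do not tell the ratio from the genotype. Leaving out hearts, the number of changed genes was 208 without wild-type replicate 1, 260 without wild-type replicate 2, 2461 without wild-type replicate 3, 164 without knock-in replicate 2 and 432 without knock-in replicate 3. Without knock-in replicate 1, the library that stood apart, 1166 genes were higher and 898 lower, against 881 and 534 with it. Upper-quartile scaling gave 594 higher and 734 lower genes, or 44.7% higher.

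**Figure D3:**
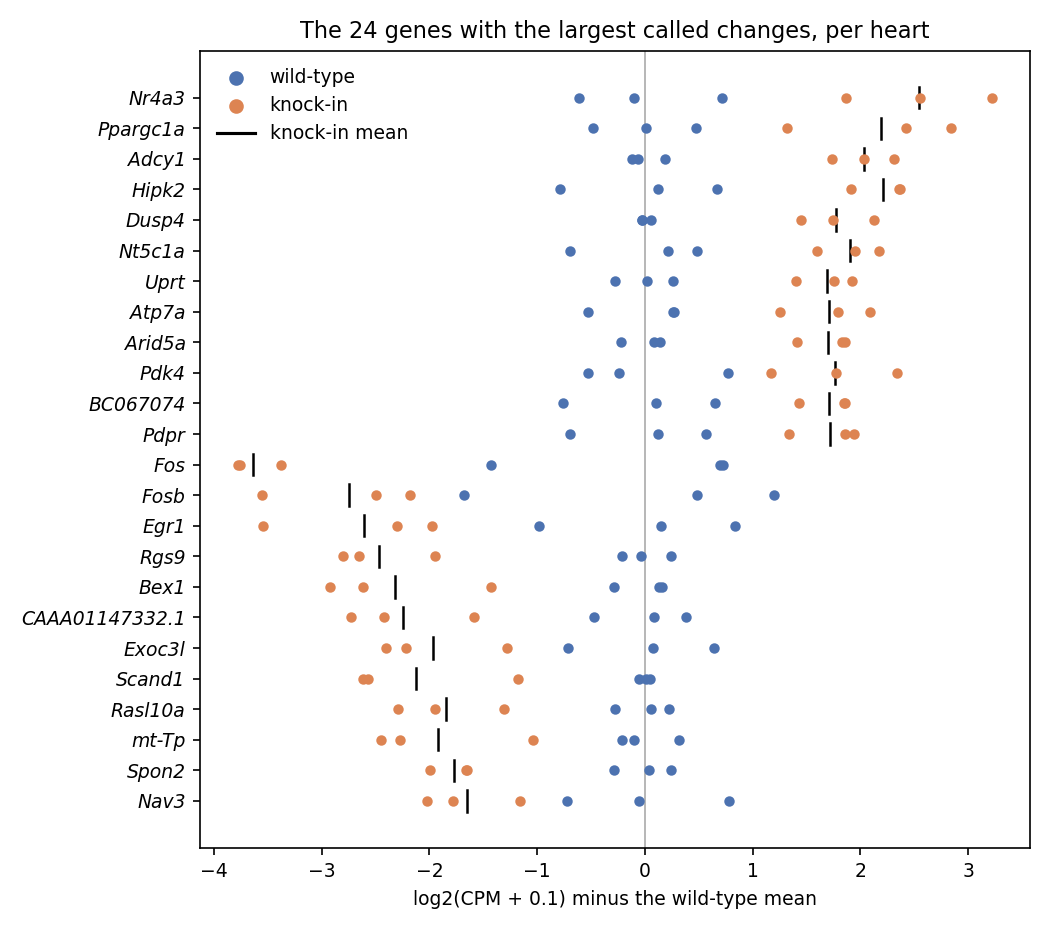
Per-heart levels of the 24 genes with the largest called changes, as log2(CPM + 0.1) minus the wild-type mean, with a black tick at the knock-in mean. Fos is lower by 4.05 and Nr4a3 higher by 2.59 on the fitted log2 scale, and the groups do not overlap for any gene drawn, since the rule for naming them required it.

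Interferon-stimulated genes were lower in knock-in hearts. Of 29 tested members, 15 fell, none rose and 14 did not pass over all genes, while 22 fell when adjusted over the list alone. Bst2 fell from 28.5 ± 6.54 to 13.7 ± 1.70 CPM (SD, n = 3 per group, edgeR adjusted p = 0.00625). Ifi44, Ifi27l2a and the immunoproteasome subunit gene Psmb8 fell 2.51-fold, 1.94-fold and 1.89-fold. The median log2 change was -0.79 (camera adjusted p = 8.88e-12), with adjusted p = 0.627 with an estimated correlation. The 3' to 5' ratio separated the groups here as for every list, and with bins near the 3' end only the list median was -0.69 (camera adjusted p = 2.42e-09, and 9.64e-14 to 0.627 over all alternatives). Markers of platelets fell with them, 3 of 4 tested members over all genes and 4 when adjusted over the list alone, with Ppbp 2.98-fold, Itga2b 2.57-fold and Pf4 1.67-fold lower. The platelet list had camera adjusted p = 0.00250, adjusted p = 0.627 with an estimated correlation and 0.00981 with 3' end bins only, 0.000268 to 0.627 over all alternatives. Markers of endothelial cells had a median of -0.34. For these markers, camera gave an adjusted p = 0.0217, adjusted p = 0.807 with an estimated correlation, 0.0202 with 3' end bins only, 0.00361 to 0.807 over all alternatives. In all, 2 of 13 fell, Cldn5 and Emcn, against 5 when adjusted over the list alone. The endothelial call was lost without wild-type replicate 1 (median -0.169, camera adjusted p = 0.110) and without knock-in replicate 1 (median -0.167, 0.293). The mean log2 CPM of the endothelial markers, centred over the hearts, was 0.41 and -0.43 in these hearts. It ran from -0.08 to 0.06 in the others. Lyz2, a macrophage gene, fell 1.54-fold. The smooth muscle genes Tagln, Acta2 and Cnn1 fell 1.77-fold, 1.87-fold and 3.44-fold. Of 13 tested markers of smooth muscle and pericytes, 3 were lower, 1 was higher and 9 did not pass. When adjusted over the list alone, 4 were lower and 1 was higher. The mean log2 CPM of these markers, centred over the hearts, overlapped between the groups. It was 0.28, 0.15 and 0.02 in the wild-type hearts and -0.53, -0.007 and 0.09 in the knock-in hearts. Neither the macrophage list (3 of 15 lower, 4 when adjusted over the list alone, camera adjusted p = 0.141) nor the smooth muscle list (0.115) passed. Both passed as lower without knock-in replicate 3 (0.0187 for each), and the macrophage list also with 3' end bins only (0.0202) and with the highest bin of each gene (0.000283). Over the alternatives run, adjusted p ranged up to 0.807 for the macrophage list and 0.929 for the smooth muscle list. Inflammation and chemokine genes had a median of -0.25, with 1 of 23 lower, Cxcl9, and none when adjusted over the list alone (camera adjusted p = 0.0249, adjusted p = 0.627 with an estimated correlation, 0.0883 with 3' end bins only, 0.00663 to 0.627 over all alternatives, 0.0908 without wild-type replicate 2 and 0.0697 without knock-in replicate 2). Without knock-in replicate 2, Ifi44, Ifi27l2a, Psmb8, Ppbp, Itga2b, Pf4, Cldn5, Emcn, Acta2 and Cxcl9 lost their calls (edgeR adjusted p = 0.0510 to 0.111). So did Ppbp, Itga2b, Pf4, Acta2 and Cxcl9 without knock-in replicate 3 (0.0569 to 0.0830), and these with Psmb8 without wild-type replicate 2 (0.0806 to 0.154). Psmb8, Pf4, Emcn, Acta2, Cnn1 and Cxcl9 did without wild-type replicate 1 (0.0600 to 0.143), and Cxcl9 without knock-in replicate 1 (0.0603). With 3' end bins only, Ifi44, Psmb8, Pf4, Emcn, Acta2 and Cxcl9 lost their calls (edgeR adjusted p = 0.0556 to 0.281). With the highest bin, Ifi44, Psmb8, Ppbp, Pf4, Tagln, Acta2 and Cxcl9 lost theirs (0.0542 to 0.174). After length and GC correction, Cldn5 and Acta2 did not pass (0.0688 and 0.164).

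The list of circadian clock genes was higher in knock-in hearts. Of 22 tested members, 7 rose, 1 fell and 14 did not pass over all genes, and 10 rose and 1 fell when adjusted over the list alone. Cry2, a repressor of the clock, rose from 15.4 ± 0.408 to 27.7 ± 1.94 CPM (SD, n = 3 per group, edgeR adjusted p = 0.00525). Rora, Hlf and Nr1d2 rose 2.08-fold, 2.01-fold and 1.63-fold, Nr1d2 not past the threshold without wild-type replicate 1 or 2 or knock-in replicate 2 (0.0536 to 0.0650). Arntl, the activator that partners Clock, was the member that fell, with a log2 change of -1.14 ± 0.30 (SE, edgeR adjusted p = 0.0334). It was chosen after its values were seen, and its adjusted p ranged from 0.000609 to 0.632 over the alternatives run, the latter with the 3' to 5' ratio as covariate, and of the fits with 1 heart left out it passed only in that without knock-in replicate 1. The list's median was 0.41. For clock genes, camera gave an adjusted p = 0.000298, adjusted p = 0.515 with an estimated correlation, 0.0233 with 3' end bins only, 2.06e-05 to 0.515 over all alternatives.

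Of the lists of fuel use, those of fatty acid oxidation, the tricarboxylic acid cycle, glycogen and mitochondrial biogenesis passed as higher in knock-in hearts, although most members of each did not pass. The list of ketone and branched-chain amino acid catabolism had a median of -0.06 and did not pass (camera adjusted p = 0.524), except as lower with the 3' to 5' ratio as covariate (0.0212, and up to 0.908 over the alternatives run). In fatty acid uptake and oxidation, 9 of 41 members rose and none fell, against 11 and 1 when adjusted over the list alone. Decr1, an auxiliary enzyme of beta-oxidation, rose from 408 ± 19.6 to 610.5 ± 21.5 CPM (SD, n = 3 per group, edgeR adjusted p = 0.00653). Without wild-type replicate 1, Decr1 had an edgeR adjusted p = 0.0557. Acsl1, Slc25a20 and Hadha rose 1.62-fold, 1.39-fold and 1.38-fold. The list had camera adjusted p = 0.00250, adjusted p = 0.627 with an estimated correlation and 0.000823 with 3' end bins only, 0.000268 to 0.627 over all alternatives. In pyruvate entry and the tricarboxylic acid cycle, 8 of 35 rose and 1 fell (Mpc2, chosen after its values were seen), against 11 and 1 when adjusted over the list alone, with Got2 and Ogdh 1.5-fold and Pdk1 1.61-fold higher. For this cycle, camera gave an adjusted p = 0.0240, adjusted p = 0.627 with an estimated correlation, 0.00148 with 3' end bins only, 0.00148 to 0.746 over all alternatives. In glycogen metabolism, 6 of 20 rose and 1 fell, against 9 and 1 when adjusted over the list alone, with the phosphorylase gene Pygb 1.79-fold and Phkb 1.62-fold higher and Ugp2 1.46-fold lower. For glycogen metabolism, camera gave an adjusted p = 0.0153, adjusted p = 0.671 with an estimated correlation, 0.0461 with 3' end bins only, 0.00282 to 0.671 over all alternatives. In mitochondrial biogenesis and dynamics, 8 of 29 rose, also when adjusted over the list alone, among them the nuclear receptors Ppara (2.68-fold) and Esrrg (1.80-fold) and the fusion gene Mfn2 (1.61-fold), whose log2 change was -0.04 with 3' end bins only. With those bins Ppara was at 1.17 and Esrrg at 0.18, neither past the threshold (edgeR adjusted p = 0.108 and 0.859). For the biogenesis list, camera gave an adjusted p = 0.00575, adjusted p = 0.627 with an estimated correlation, 0.0264 with 3' end bins only, 0.000594 to 0.838 over all alternatives. Acsl1, Slc25a20, Hadha, Ogdh, Pdk1, Phkb, Esrrg and Mpc2 lost their calls without wild-type replicate 1 or 2 or knock-in replicate 2 (edgeR adjusted p = 0.0524 to 0.108), and Esrrg and Mpc2 also without knock-in replicate 3 (0.0607 and 0.0638). Got2 did without wild-type replicate 1 or knock-in replicate 2 (0.0594 and 0.0544), Ugp2 without wild-type replicate 2 or knock-in replicate 2 (0.0539 and 0.0888), and Ppara without knock-in replicate 1 (0.0530). With 3' end bins only, Ogdh, Acsl1, Got2 and Mpc2 lost their calls (edgeR adjusted p = 0.0543 to 0.440). They stood there at 0.21, 0.27, 0.38 and -0.18 on the log2 scale. With the highest bin, the same genes and Hadha, Phkb, Ugp2 and Mfn2 lost theirs (edgeR adjusted p = 0.0669 to 0.443). Glucose uptake and glycolysis did not pass as a list (camera adjusted p = 0.520), and 4 of 27 members rose, also when adjusted over the list alone, among them Slc16a1, Pfkm and Hk2. These 3 lost their calls with 3' end bins only, where Hk2 was at 0.02 on the log2 scale, with the highest bin and with upper-quartile scaling. They did so too without wild-type replicate 1 or 2 or knock-in replicate 2 or 3 (edgeR adjusted p = 0.0688 to 0.183).

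The lists that follow were higher in knock-in hearts, and each lost its call with 3' end bins only. Insulin signalling genes, with a median exonic length of 7676 bases, had 11 of 35 members higher, and 18 when adjusted over the list alone, with Pik3r1 2.03-fold, Foxo3 1.91-fold and Prkaa2 1.84-fold higher. The list had camera adjusted p = 2.89e-05, adjusted p = 0.627 with an estimated correlation and 0.0541 with 3' end bins only, 3.27e-07 to 0.823 over all alternatives. Calcium handling genes had 10 of 25 members higher, and 12 higher and 1 lower when adjusted over the list alone, with the sodium-calcium exchanger gene Slc8a1 2.5-fold, Cacna1c 1.82-fold and Cacna2d1 2.10-fold higher. For calcium handling, camera gave an adjusted p = 0.000385, adjusted p = 0.627 with an estimated correlation, 0.248 with 3' end bins only, 1.63e-05 to 0.746 over all alternatives. Nedd4-family ligases and adaptors had 1 of 11 members higher, Nedd4 (1.76-fold), and 3 when adjusted over the list alone, with Itch at 0.51 ± 0.17 and Wwp1 at 0.39 ± 0.13 (log2, SE) not past the threshold. Nedd4 itself was at 0.08 on the log2 scale with 3' end bins only and 0.03 with the highest bin (edgeR adjusted p = 0.730 and 0.929), and at -0.14 with the 3' to 5' ratio as covariate (0.996, the highest over its alternatives). Its call was also lost without wild-type replicate 1 or 2 or knock-in replicate 2 (0.0583 to 0.0621). The ligase list had camera adjusted p = 0.0402, adjusted p = 0.627 with an estimated correlation and 0.231 with 3' end bins only, 0.0196 to 0.929 over all alternatives. The list's call was lost without any 1 of wild-type replicates 1 and 2 and knock-in replicates 1 and 3 (camera adjusted p from 0.0634 to 0.0908). Hypoxia-inducible genes had 3 of 24 members higher, Plod2 and the metabolic genes Pdk1 and Hk2, and 4 when adjusted over the list alone (camera adjusted p = 0.0391, adjusted p = 0.732 with an estimated correlation, 0.116 with 3' end bins only, 0.0168 to 0.948 over all alternatives). With 1 heart left out, the call held only without wild-type replicate 2 or knock-in replicate 1, with 0.0503 to 0.0873 otherwise. Prkaa2, Plod2 and Pdk1 lost their calls without wild-type replicate 1 or 2 or knock-in replicate 2 (edgeR adjusted p = 0.0531 to 0.0737), Hk2 without these or knock-in replicate 3 (0.134 to 0.183), and Cacna2d1 without knock-in replicate 2 (0.0510). Plod2 was at 0.21 on the log2 scale with 3' end bins only and 0.15 with the highest bin (edgeR adjusted p = 0.543 and 0.635). Cacna1c was at 0.42 and 0.36 in these fits (0.195 and 0.199), and Pik3r1 at 0.39 and 0.34 (0.0659 and 0.0977). Cacna2d1 was at 0.17 with the highest bin (0.631).

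Some lists of shorter genes were lower in knock-in hearts, and the 3' to 5' ratio separated the groups for them too. The mean log2 CPM of members, centred over the hearts, overlapped between the groups for mitochondrial ribosome, complex I and cytosolic ribosomal protein genes. Knock-in replicate 1 was at 0.03, 0.11 and 0.15 for these lists, above wild-type replicate 3 at 0.005, -0.04 and -0.06. Mitochondrial ribosome genes had 7 of 39 members lower, among them Mrpl34 (1.78-fold) and Mrps12 (1.8-fold), and 10 when adjusted over the list alone. For the mitochondrial ribosome, camera gave an adjusted p = 3.37e-05, adjusted p = 0.732 with an estimated correlation, 0.426 with 3' end bins only, 7.03e-07 to 0.732 over all alternatives. Nuclear genes of respiratory complex I, with a median exonic length of 1293 bases, had 4 of 34 members lower, also when adjusted over the list alone, among them Ndufab1 (1.65-fold) and Ndufs7 (1.57-fold). The complex I list had a median of -0.12 (camera adjusted p = 0.0240, adjusted p = 0.908 with an estimated correlation, 0.000295 to 0.908 over all alternatives) and 0.06 with 3' end bins only. With the 3' to 5' ratio as covariate it passed as higher (0.0207). Its call was lost without any 1 of wild-type replicates 1 and 2 and knock-in replicates 2 and 3 (0.0839 to 0.269). Complexes II to V did not pass (camera adjusted p = 0.106), with 5 of 42 members lower, Cox6a1, Cox8a, Cox5b, Atp5g3 and Cox5a (the last chosen after its values were seen), and 1 higher and 6 lower when adjusted over the list alone. That list passed as lower with DESeq2 (0.0119), limma-voom (0.0232), without wild-type replicate 3 (0.0318) and without knock-in replicate 1 (0.00147), and as higher with the ratio as covariate (0.0347), with up to 0.908 over the alternatives run. The cytochrome c oxidase subunit genes Cox6a1, Cox8a and Cox5b fell 2.35-fold, 2.20-fold and 1.82-fold. With 3' end bins only, Cox5b, Atp5g3 and Cox5a lost their calls (edgeR adjusted p = 0.158, 0.466 and 0.782). They stood there at -0.36, -0.15 and -0.07 on the log2 scale. Ndufab1, Ndufs7, Mrpl34, Mrps12 and Rpl13 also lost their calls with those bins (0.0760 to 0.669). With the highest bin, Cox5b was at -0.35 (edgeR adjusted p = 0.154). Cytosolic ribosomal protein genes had 1 of 43 members lower, Rpl13, and none when adjusted over the list alone (camera adjusted p = 0.0147, adjusted p = 0.908 with an estimated correlation, 1.17e-05 to 0.929 over all alternatives), and a median of -0.15, or 0.02 with 3' end bins only. With the ratio as covariate this list passed as higher (0.0136). The ribosomal protein call was lost without wild-type replicate 2 (0.0957), knock-in replicate 2 (0.110) or knock-in replicate 3 (0.297). Mrpl34, Mrps12, Ndufs7, Atp5g3, Cox5a and Rpl13 lost their calls without wild-type replicate 1 or 2 or knock-in replicate 2 or 3 (edgeR adjusted p = 0.0771 to 0.172). Ndufab1 did without wild-type replicate 2 or knock-in replicate 2 (0.0536 and 0.0636), and Cox5b without knock-in replicate 2 (0.0598).

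Immediate early genes, which respond to stimulation within minutes, had 9 of 24 members lower and 1 higher, and 12 lower and 5 higher when adjusted over the list alone. Besides Fos, Fosb and Egr1, Ier2 fell 3.46-fold and Ccn1 fell 1.80-fold, while Nr4a3 rose. The list median was -0.74. For immediate early genes, camera gave an adjusted p = 0.0191, adjusted p = 0.732 with an estimated correlation, 0.496 with 3' end bins only, 3.83e-05 to 0.732 over all alternatives. With the ratio as covariate the list passed as higher, with a median of 0.55 (0.0212). The call was lost without wild-type replicate 1 (0.0537) or wild-type replicate 2 (0.0807). Cardiac stress and fetal genes had 6 of 18 members lower and 2 higher, and 8 lower and 2 higher when adjusted over the list alone. Nppb, the gene of B-type natriuretic peptide, fell from 227 ± 44.8 to 118 ± 43.1 CPM (SD, n = 3 per group, edgeR adjusted p = 0.0189). Nppb passed only without wild-type replicate 3 or knock-in replicate 1 (0.0709 to 0.103 otherwise). Nmrk2 and Ankrd1 fell 3.33-fold and 1.43-fold, and Ccn2 rose 1.81-fold. Ankrd1 lost its call without wild-type replicate 1 or 2 or knock-in replicate 2 or 3 (0.0626 to 0.105), and Ccn2 without wild-type replicate 1 or knock-in replicate 2 or 3 (0.0535 to 0.0850). The stress list had camera adjusted p = 0.0391, adjusted p = 0.627 with an estimated correlation and 0.0109 with 3' end bins only, 0.00731 to 0.627 over all alternatives. The stress list's call was lost without wild-type replicate 2 or 3 or knock-in replicate 2 or 3 (0.0503 to 0.122). The skeletal muscle genes Acta1 and Myl1 fell 2.85-fold and 1.70-fold, with the list of skeletal muscle markers not past the threshold (camera adjusted p = 0.150). Acta1 did not pass without wild-type replicate 1 or knock-in replicate 2 or 3 (edgeR adjusted p = 0.0576 to 0.116). Glucocorticoid-responsive genes did not pass as a list (camera adjusted p = 0.524). Of 19 members, 3 rose, Zbtb16 (2.38-fold), Klf9 (1.51-fold) and Pdk4, and 2 fell, Errfi1 (1.84-fold) and Cdkn1a (1.77-fold, chosen after its values were seen), against 3 and 3 when adjusted over the list alone. The mean log2 CPM of its members, centred over the hearts, was lowest in wild-type replicate 3 (-0.59, against 0.02 to 0.24 in the others), and its median was 0.11 with that heart and -0.15 without it. With the 3' to 5' ratio as covariate the list passed as higher (camera adjusted p = 7.53e-08, and up to 0.908 over the alternatives run). Klf9 and Errfi1 did not pass without wild-type replicate 1 or 2 or knock-in replicate 2 (edgeR adjusted p = 0.0562 to 0.0986), nor Cdkn1a without these or knock-in replicate 3 (0.0998 to 0.134). The red blood cell gene Hbb-bs rose 1.67-fold, with its list not past the threshold (camera adjusted p = 0.184). That list passed as higher with 3' end bins only (0.0139), with the highest bin (0.0258) and without knock-in replicate 2 (0.0115), with up to 0.908 over the alternatives run. Hbb-bs itself lost its call without wild-type replicate 1 or 2 or knock-in replicate 1 or 3 (edgeR adjusted p = 0.0764 to 0.166).

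**Figure D4:**
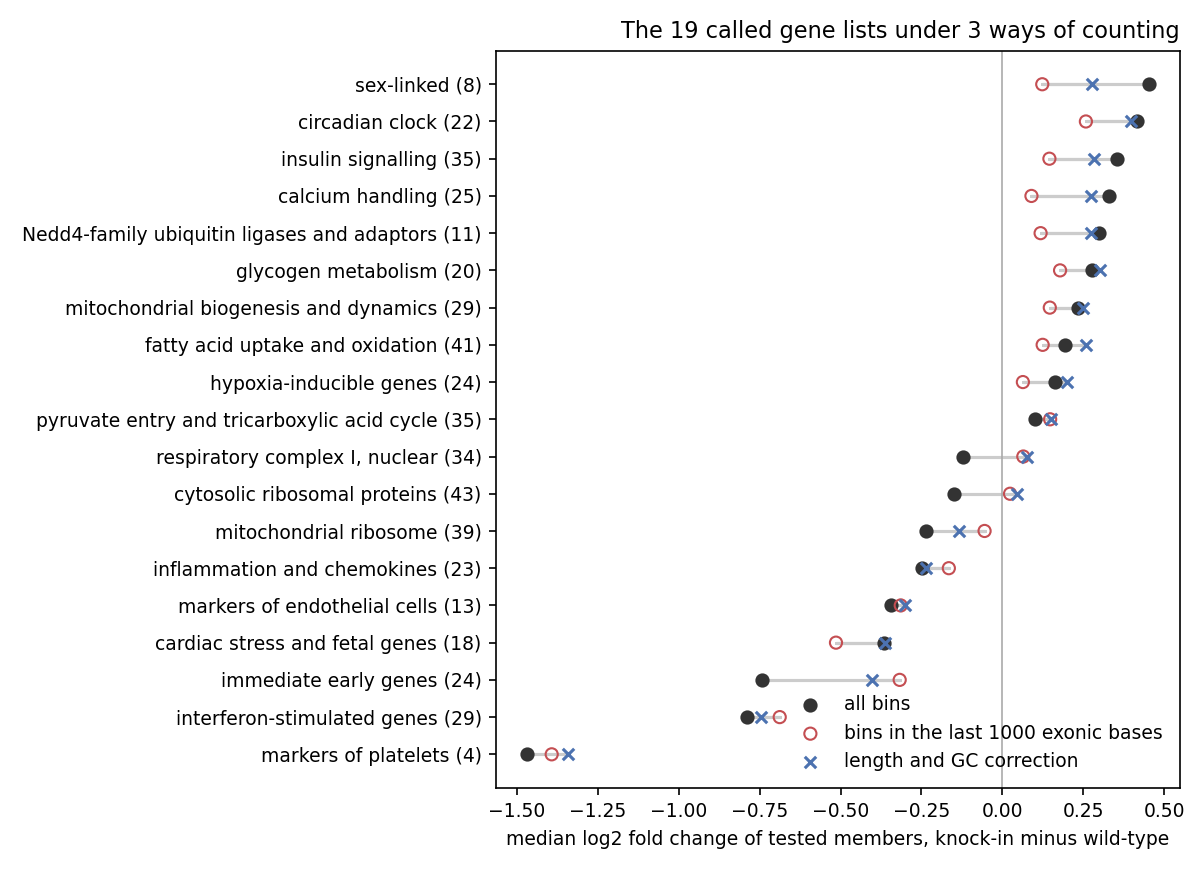
Median log2 fold change, knock-in minus wild-type, of the 19 gene lists past the camera threshold, with the number of tested members in brackets, from all bins (filled), from bins in the last 1000 exonic bases (open) and after length and GC correction (crosses). The interferon-stimulated list stays between -0.79 and -0.69, while nuclear complex I moves from -0.12 to 0.06 and 0.08.

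Among the other alpha-arrestins, Arrdc3 rose from 20.7 ± 1.46 to 29.3 ± 3.59 CPM (SD, n = 3 per group, edgeR adjusted p = 0.0351). With 1 heart left out, Arrdc3 passed only without wild-type replicate 3 or knock-in replicate 1 (0.0900 to 0.176 otherwise). It was at 0.32 on the log2 scale with 3' end bins only and 0.26 with the highest bin (edgeR adjusted p = 0.279 and 0.318). Its call was also lost after length and GC correction (0.0701) and with upper-quartile scaling (0.0597). Arrdc4, Arrdc2 and Arrdc1 had log2 differences of -0.27 ± 0.24, -0.66 ± 0.63 and -0.04 ± 0.34 (SE) and did not pass. The alpha-arrestin list had camera adjusted p = 0.808, with 1 of 5 members higher over all genes and 1 higher and 1 lower when adjusted over the list alone. With 3' end bins only, where Txnip, which is 1 of its members, was higher, the list passed as higher (0.0301, and up to 0.968 over the alternatives run). Within 5 Mb of Txnip, 12 of 98 tested genes (12.2%) were called against 10.8% elsewhere, which did not pass (Fisher's exact test, two-sided, p = 0.624, odds ratio 1.15 with a 95% interval of 0.571 to 2.12). That count was 1 without wild-type replicate 1 or 2, 0 without knock-in replicate 2 and 2 without knock-in replicate 3. Those fits also called fewer genes in all, 208, 260, 164 and 432. The range over every fit with 1 heart left out is given below. Of the 12 genes called with all hearts, 10 were higher, against 62.3% of all calls. Sex-linked genes had 2 of 8 members higher, Eif2s3x and Ddx3y, and 3 when adjusted over the list alone, both lost without wild-type replicate 1 or 2 or knock-in replicate 2 or 3 (edgeR adjusted p = 0.0810 to 0.167), with Uty, Ddx3x, Kdm6a, Kdm5c, Eif2s3y and Kdm5d not past the threshold. Eif2s3x was at 0.26 and Ddx3y at 0.07 on the log2 scale with 3' end bins only (edgeR adjusted p = 0.368 and 0.879). Both also lost their calls with the highest bin (0.442 and 0.336). For the sex-linked list, camera gave an adjusted p = 0.0147, adjusted p = 0.732 with an estimated correlation, 0.284 with 3' end bins only, 0.00239 to 0.732 over all alternatives. Myh6, whose promoter is commonly used to drive MerCreMer in heart muscle, had a log2 difference of 0.39 ± 0.12 (SE, edgeR adjusted p = 0.0603), Greb1 of -0.07 ± 0.57, and Esr1 fell by 0.37 on the log2 scale (edgeR adjusted p = 0.0306, and 0.0782 to 0.146 without wild-type replicate 1 or 2 or knock-in replicate 2 or 3). Of genes known to vary between mouse strains, Nnt, Glo1 and Wdfy1 had log2 differences of 0.36 ± 0.12, 0.20 ± 0.11 and 1.07 ± 0.58 (SE). None passed the threshold, nor did their list (camera adjusted p = 0.141). Their mean log2 CPM, centred over the hearts, did not overlap between the groups. It was -0.99, -0.26 and 0.16 in the wild-type hearts and 0.40, 0.35 and 0.34 in the knock-in hearts. A difference in strain background was not tested.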

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

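The tests of swapped or wrong labels, of slopes within groups, of the length and GC correction and of 3' end bins were chosen only after the result was seen. The Txnip 3' UTR drew attention as a signal that the comparison of gene totals does not use: its counts per base were 17.9% ± 2.68 of those of the short coding bins in knock-in hearts and 0.495% ± 0.0628 in control hearts (SD, n = 3 per group). Reads are counted in each short bin they span, which lowers both percentages.

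Poor 3' coverage of the wild-type libraries is argued against for the Txnip 3' UTR, since its shift of 5.11 on the log2 scale lay at percentile 100 of 5040 other genes, whose highest was 1.49 (Cox5b). A swapped or wrong label of part of the libraries is argued against as well, since the gap between the groups was 10.9 times the larger range within a group. An exchange of all labels would give the same gap, so it stays open. A candidate explanation that stays open is another 3' end of the floxed Txnip allele in the control hearts, which was not tested because the sequence of the allele was not used here. A change in 3' end use that comes with the knock-in genotype stays open too and was not tested.

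Nuclear respiratory chain genes had a median log2 change of -0.094 over 76 tested members. A lower share of cardiomyocytes cannot be told apart for these genes. Markers of ventricular cardiomyocytes went both ways, with a median of 0.023 and quartiles of -0.24 and 0.17. A median of 0 or above was set beforehand to count against this cause. The quartiles, which that rule did not name, lie on either side of the respiratory median, so the markers do not decide for these genes. A trend with transcript length or GC content cannot be told apart for them either. The median was 0.086 after correction, but the bound set for the test, -0.1 or nearer 0, was already met before it. RNA degradation seen as a 3' shift of coverage met its prediction, since the lowest wild-type and the highest knock-in ratio were 0.40 apart. That test used no respiratory gene and would come out the same for any list, so it does not decide for these genes. The respiratory median was 0.084 with 3' end bins only. A difference that comes with the genotype stays open and untested, with Cox6a1 and Cox8a past the threshold as lower under each alternative run for single genes except the ratio as covariate, where they were at -0.28 and -0.45 and not past it.

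The number of genes changed, 1415, may also hold an effect of RNA degradation seen as a 3' shift of coverage. Across genes, which are not independent replicates, slopes on the 3' to 5' ratio within groups correlated with the difference between groups at 0.353, and 87.7% of called genes had the sign those slopes predict. Of 36 pairings of ratios with hearts within groups, 2, the real one included, gave a correlation as high, and the highest of the others was 0.359. The share of genes with the predicted sign was not computed over all tested genes. The slopes rest mainly on the wild-type hearts, whose ratios had an SD of 0.211 against 0.0619 in knock-in hearts. In simulated counts the same correlation was 0.186 with a ratio effect and 0.00592 without one. Those genes were drawn independently, so 0.00592 is not the level to expect without a ratio effect in real, correlated genes. The simulation thus does not decide how 0.353 is to be read. Degradation, a batch and genotype cannot be told apart for the called genes as a set. Every wild-type library had a higher ratio than every knock-in library, and the labels give no batch. The ratio alone does not tell degradation from a batch, here or for the respiratory genes.

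The 10 splits of the 6 hearts into 3 and 3 are too few for a share under 0.05. The real split gave 1415 genes and the highest other split 0, so 1 of the 10 gave as many genes. For gene lists the real split gave 19 and the highest other 17, so again 1 of the 10 gave as many.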

How the results depend on the processing

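The fits with the highest bin, 3' end bins, length and GC correction, the 3' to 5' ratio as covariate and Txnip coding bins were chosen only after the result was seen, and the cause of each change below was not tested unless stated. No paired analysis was possible because the labels give the groups no shared replicate numbers (R1 and R2 name read files). Of 103 called genes named, 35 kept their calls under every alternative fixed before the data were examined and 28 also under those added later, the ratio as covariate apart, which called none of the 1415 genes. Without wild-type replicates 1, 2 and 3 in turn, 52, 56 and 102 of the 103 kept their calls, and without knock-in replicates 1, 2 and 3, 97, 45 and 66. Of those that gave a value, 44 of 90 kept their calls with 3' end bins and 48 of 98 with the highest bin. Of 19 called lists, 6 kept them under those fixed before, fry among them but the estimated correlation apart, and 3 (interferon-stimulated, clock and platelet genes) also under the added ones that gave a value. Genes near 1 CPM, such as Fosb and Dusp4, have the least depth behind their folds.

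The genes changed in knock-in hearts (1415, with genes higher in knock-in hearts 881 and genes lower in knock-in hearts 534) numbered 245 (171 and 74) at an adjusted p under 0.01, 2395 (1404 and 991) at 0.1 and 939 (526 higher) with a 1.5-fold minimum, by construction. Lower genes numbered 877 with no filter on low counts. The count was 607 (377 and 230) with the highest bin, 388 (204 and 184) with 3' end bins and 3 (2 and 1) with the ratio as covariate, where 66.0% of the 1415 kept their sign. Leaving out 1 heart gave 164 to 2461 changed, 105 to 1544 higher and 59 to 917 lower genes. The Txnip level, at -0.60, was -0.68 with upper-quartile scaling, -0.61 with DESeq2 and -0.88 with coding bins, all past the threshold, and 4.53 with 3' end bins, which hold the 3' UTR by construction. It was -0.80 to -0.36 without 1 heart. Genes near Txnip numbered 4 within 1 Mb and 20 within 10 Mb by construction, and 0 to 17 without 1 heart. The 4, chosen after their values were seen, were Golph3l, Anp32e, Otud7b and Bcl9. Lists called numbered 9 with the highest bin, 0 of 54 with an estimated correlation in camera, 8 with fry (7 of them among the 19), and 14 to 19 without 1 heart.

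These values had the opposite sign, on the log2 scale. With 3' end bins they were 0.041 for Arrdc4, 0.30 for Arrdc1, 0.14 for Ndufab1, -0.042 for Mfn2, -0.30 for Myh6, -0.31 for Nebl, -0.089 for Uty, 0.065 for complex I and 0.024 for cytosolic ribosomal proteins. With the highest bin they were -0.32 for Myh6, -0.10 for Kdm5d and 0.015 for complex I, and cytosolic ribosomal proteins turned in camera's direction at a median of -0.011. After length and GC correction they were 0.25 for Arrdc1, -0.063 for Kdm5d, 0.076 for complex I and 0.046 for cytosolic ribosomal proteins, and Greb1 was 0.10 with limma-voom. Without 1 heart, Arrdc2 ran from -1.14 to 0.018, Arrdc1 from -0.56 to 0.26 and Greb1 from -0.48 to 0.39. With the ratio as covariate, 29 of the 103 called genes named turned sign, 21 of them reported as higher and 8 as lower, and none of the 103 passed the threshold (smallest edgeR adjusted p = 0.632; none of the 29 had an unadjusted p under 0.05). Among the 29, Pdk4 was at -0.55, Ppara at -0.41, Pdpr at -0.33, Slc8a1 at -0.31, Hipk2 at -0.086, Nt5c1a at -0.082, Fosb at 0.67 and Ier2 at 0.49. In that fit, list medians were -0.14 for glycogen, 0.20 for complex I, 0.12 for mitochondrial ribosome, 0.29 for cytosolic ribosomal proteins, -0.073 for calcium, 0.16 for inflammation, 0.55 for immediate early, -0.25 for sex-linked and 0.31 for endothelial genes, and hypoxia turned in camera's direction at 0.0064. Of these, complex I, cytosolic ribosomal proteins and immediate early genes passed the threshold as higher (camera adjusted p = 0.0207, 0.0136 and 0.0212).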

Other observations

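Ion channel and conduction genes had 8 of 30 members higher, and 8 higher and 1 lower when adjusted over the list alone. Abcc9, a subunit gene of ATP-sensitive potassium channels, rose by 1.1 ± 0.18 on the log2 scale (SE, edgeR adjusted p = 0.00580), while the list did not pass (camera adjusted p = 0.0733). It passed as higher with DESeq2 (0.0355), limma-voom (0.0475), no filter on low counts (0.0210), length and GC correction (0.0255) and without wild-type replicate 3 (0.0310), with up to 0.979 over the alternatives run. Among sarcomere genes, 5 of 28 were higher and 1 lower, and 6 and 1 when adjusted over the list alone, with Myom2 1.84-fold and Nebl 2.33-fold higher and Tpm2, a tropomyosin gene, 2.05-fold lower (camera adjusted p = 0.208, and 0.0427 with fry). With 3' end bins only, chosen only after the result was seen, Abcc9 was at 0.12 (edgeR adjusted p = 0.716), Nebl at -0.31 and Myom2 at 0.57, none past the threshold. With the 3' to 5' ratio as covariate, also chosen then, Abcc9 was at -0.079 (0.996, the highest over its alternatives) and Nebl at -0.27. The thioredoxin system, part of which Txnip binds, had none of 23 members past the threshold over all genes by edgeR or when adjusted over the list alone, with a list median of -0.017 (camera adjusted p = 0.595).

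Esr1 (chromosome 10, 4611593 to 5005614) held 99.7% to 99.8% of its counts in 6 of 31 bins, from 4856858 to 5001656, in each of the 6 hearts. Its level was 3033 ± 233 CPM in wild-type and 2343 ± 64.5 CPM in knock-in hearts (SD, n = 3 per group, edgeR adjusted p = 0.0306). MerCreMer holds sequence of the estrogen receptor. The last bin of the native gene, of 1853 bases, held 1 to 11 counts per heart and the bin before it, of 1737 bases, 1 to 5, so nearly all counts come from transcripts without the native 3' end.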
